A study of Mus musculus with 6 samples.

How the data were processed

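CGR8 mouse embryonic stem cells were differentiated as embryoid bodies, cell aggregates in which the germ layers form, and were sorted by flow cytometry on day 5 for the surface proteins CXCR4 and FLK-1, per the labels. FLK-1 is the product of Kdr. The labels give 3 samples positive for both proteins (double positive) and 3 negative for both (double negative), collected independently. Biotinylated cRNA made from 6 ug of total RNA was hybridised to Affymetrix Mouse 430 2.0 arrays, 1 array per sample, per the labels' protocols. The series text calls the profiled material RNA pools without saying what was pooled. If samples of a pool shared cells, the p-values below measure the spread between these pools.

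The deposited value table holds linear ratios for 45101 probe sets on 6 arrays. The median of the 3 double-negative arrays is 1 for 100% of probe sets, so the authors divided each probe set by that median. The software that summarised the probes, any background correction and any scaling of whole arrays are not given in the sources used here. The ratios run from 0.01 to 67.67 and keep no brightness, so signal over background is unknown, and the number of arrays limits the precision. A second deposited table, the authors' comparison, lists a fold change, a p-value and a flag score for 22584 probe sets, of which 22526 are not Affymetrix controls. Its fold is the ratio of the geometric group means of the deposited values, double positive over double negative, for 100% of probe sets within a tolerance of 1%. Its p-values match a Welch test on log ratios within 0.005 for 99.97% of probe sets. Per the file headers, the flag score is a flag pass value. It is a whole number from 2 to 6 and was read here as the number of arrays on which the probe set was detected.

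Gene names come from the authors' comparison table and were updated through RefSeq gene names (GRCm38.p6), used for names only. A current symbol was found for 11508 probe sets as given and for 8667 through a synonym. The name was kept as given for 1128 probe sets. A further 125 had several candidate genes and 1156 had no name, and these were not assigned to a gene. The 12263 named genes each stood by 1 probe set, the one with the highest flag score, then by the plainest identifier and then by the lowest. For 5170 genes there were several probe sets to choose from. Probe sets outside the authors' comparison table are counted below but unnamed here.

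The ratios were taken to log2 without a pseudocount, and 64 control probe sets were left out. The design fixed before the data were examined had foreseen brightness values with a pseudocount at the 10th percentile, a choice among probe sets of a gene by mean brightness and filters on dim probe sets. The ratios carry none of that information. The pseudocount (0.437), a smaller one (0.109) and one 4 times as large (1.75) were therefore run as alternatives. A pseudocount shrinks differences between low ratios most, so it reduces the genes lower in double-positive cells more than the higher ones. The probe set rule was replaced as above, and the brightness filters were not run and gave way to filters on the flag score.

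Differences are double positive minus double negative. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test) over all 6 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given as SE come from that fit on the log2 scale, and n is 3 arrays per group. Where genes detected on all 6 arrays were tested with the replicate number as a block, SE comes from that blocked fit instead. The sorted genes and 28 other gene lists, holding 469 different genes in all, were fixed before the data were examined, as were the threshold, the tests and most of the other settings tried. Members of each list were adjusted over all 12263 genes and over the list alone. The shift of a list against all other genes was tested with limma's camera at a preset correlation of 0.01 for the 28 lists with at least 5 measured genes. Camera with an estimated correlation was an alternative. The rotation test fry was also run; it tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. The rule for naming genes was fixed before the data were examined: Cxcr4 and Kdr, then the 10 largest differences each way among genes past the threshold without overlap between groups, then up to 4 members per list past the threshold or else the 2 with the largest difference. Genes without a conventional name, such as predicted genes and cDNA clones, were skipped in the ranking by difference. No gene passed the threshold over all genes. The 10 largest each way with the threshold set aside, members past the threshold over their list alone or with the block, and genes past it in the blocked test of well-detected genes were named after their values were seen. Results for some genes chosen by these rules are not reported here.

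The replicate numbers in the labels were checked as pairs before calls were compared. Over the probe sets of the authors' comparison table, deviations from the group mean correlated between same-numbered arrays at 0.49, 0.34 and 0.21 for replicates 1, 2 and 3 (across probe sets, which are not independent). All exceed 0.1, so the numbers were taken to pair the samples. Differently numbered arrays correlated as highly as the third pair in 2 cases, 0.21 for double-positive replicate 3 with double-negative replicate 2 and 0.22 for double-positive replicate 2 with double-negative replicate 3, so the value of the third pair does not set it apart. Over all probe sets the values were 0.26, 0.14 and 0.055, and the third falls short. Deviations from a group mean are tied to each other, so replicate 1 arrays that stand apart also raise values among replicates 2 and 3. The difference between replicates 2 and 3, which leaves replicate 1 out, correlated at 0.056 between the groups. The pairing is thus not shown beyond replicate 1, and calls with the block assume it. The labels do not say that a number marks a shared culture. Values with the replicate number as a block are given where they end or add a call of a list or move a count of calls. Each array's integrity was read from the 5'/3' ratios of its Actb and Gapdh control probe sets.

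The tests were tested on simulated data with the 12263 genes and spread of these arrays, in 10 simulations. Pair effects and spread were taken from the blocked fit of these arrays, so pairing was built into every simulated set. The gain with the block was thus fixed in advance and does not show that the block suits these data. At the same threshold, the test without block recovered 0% of genes changed by 1 on the log2 scale, 3.4% at 2 and 50.8% at 3. With the block the shares were 1.5%, 62.1% and 90.8%. The false calls over all 10 simulations were 6 without and 61 with the block. Alternatives covered quantile normalization, median centring, the pseudocounts, a variance model with trend and robust fitting, array weights, the block, the mean over a gene's probe sets, a stricter threshold and each array left out in turn. The trend of that variance model follows a gene's mean log2 ratio. Double-negative ratios lie around 1, so this mean moves with the group difference. The model can thus assign a larger variance to genes with large differences, and its lower counts cannot weigh the calls by themselves.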

Results

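The series set cells carrying both CXCR4 and FLK-1 on day 5 of embryoid body differentiation against cells carrying neither, to find transcripts that differ between these fractions. Each fraction was profiled on 3 arrays. Values are ratios to the double-negative median of each probe set, so they compare arrays and give no absolute level of a transcript.

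Transcripts of both sorted proteins were more abundant in the double-positive cells. Cxcr4, the receptor of the chemokine Cxcl12, stood at ratios of 5.405, 8.044 and 6.006 in double-positive replicates 1 to 3, against 0.783, 1.954 and 1 in the double-negative ones. That is a 5.55-fold difference (95% confidence interval 2.88 to 10.7, log2 difference 2.47, SE 0.415, n = 3 per group). Kdr, which encodes FLK-1, a receptor of vascular endothelial growth factor, stood at 4.943, 13.39 and 10.44 against 1, 3.929 and 0.75. It was 6.17-fold higher (95% confidence interval 2.19 to 17.4, log2 difference 2.62, SE 0.655). Both were higher in 3 of 3 replicate pairs, and double-negative replicate 2 had the highest level of both among the double-negative arrays. Both rose when adjusted over the list alone (limma moderated test, Benjamini-Hochberg adjusted p = 0.000538 for Cxcr4 and 0.00347 for Kdr). Over all genes neither passed, with limma adjusted p = 0.22 for Cxcr4 and 0.519 for Kdr.

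**Figure D1:**
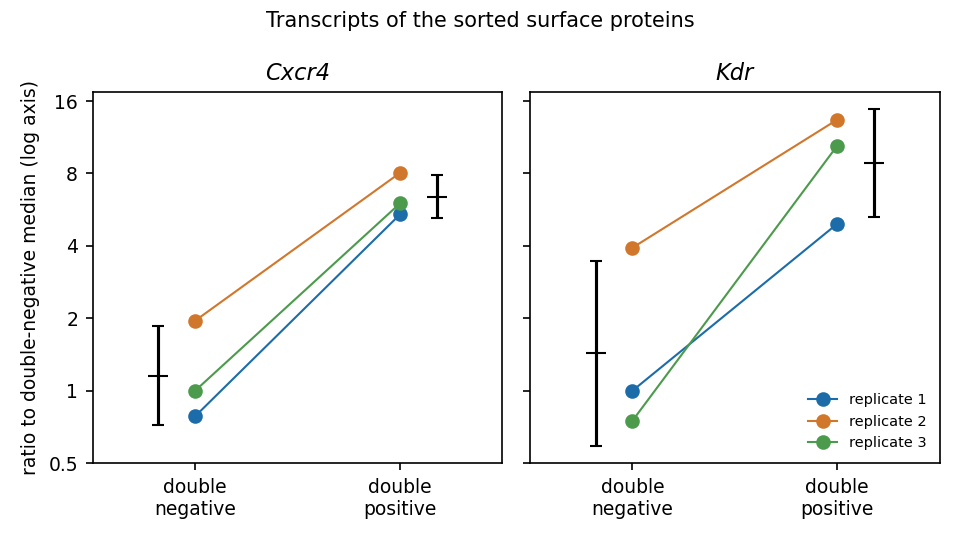
Ratio of Cxcr4 (left) and Kdr (right) to the double-negative median of the probe set, on a log axis, in the 3 double-negative and 3 double-positive arrays; lines join arrays with the same replicate number, and black bars give the mean and SD of log2 ratios. Cxcr4 lay between 5.405 and 8.044 in the double-positive arrays, above all double-negative values, and Kdr lay between 4.943 and 13.39.

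Among conventionally named genes whose groups did not overlap, the largest differences outside the sort genes belonged to Ackr3, Asb4 and Pcsk5 on the higher side. Ackr3, a second receptor of Cxcl12 that does not signal through G proteins, was 9.89-fold higher in double-positive cells (log2 difference 3.31, SE 0.484). Asb4 was 9.33-fold higher (3.22, SE 0.397) and the proprotein convertase Pcsk5 7.49-fold higher (2.90, SE 0.589). Phlda2, Myzap, Trim54, Pcdh12 and the atrial myosin light chain Myl7 completed that side together with Cxcr4 and Kdr, with log2 differences between 2.47 and 2.62. Some were uneven over replicate pairs 1 to 3, with Pcdh12 at 4.849, 1.167 and 1.468 and Trim54 at 2.552, 0.739 and 4.217. On the lower side stood the arginase Arg1 at -4.05 (SE 0.895), Arntl2 at -3.84 (SE 0.987) and the fatty acid receptor Cd36 at -3.57 (SE 0.857). Thsd4, H2-Q1, Morc1, the cholesterol transporter Abcg1, Cobl, Scn9a and Rab6b followed, between -3.39 and -2.94. Here too some were uneven over the pairs, with Rab6b at -5.487, -1.576 and -1.741 and Arntl2 at -5.229, -5.442 and -0.857. A pseudocount of 1.75, which shrinks ratios under 1 most, brought Arg1 to -0.59, Arntl2 to -0.51 and Cd36 to -0.68, and Ackr3 to 2.12 and Asb4 to 1.97. H2-Q1 has close paralogs whose transcripts the probes can share, and 1 other probe set of Scn9a and 1 of Rab6b pointed the other way. Thsd4 and Cobl passed detection flags on 2 of the 6 arrays, H2-Q1, Abcg1, Scn9a and Trim54 on 3, and Arg1, Arntl2, Morc1, Rab6b, Ackr3, Pcsk5, Pcdh12 and Myl7 on 4.

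None of these genes passed the adjustment over all 12263 genes in the limma moderated test, where 0 genes reached the threshold and the smallest adjusted p was 0.17. At an unadjusted p under 0.05 there were 629 genes, 210 higher and 419 lower, where chance gives 613. That balance depended on the scale, with 78 higher and 344 lower after quantile normalization and 385 higher and 346 lower with a pseudocount of 1.75. Quantile normalization acted here on ratios already divided by the double-negative median, not on brightness. Over the probe sets of the authors' comparison table the SD of log2 ratios was 0.593 to 0.838 in the double-positive arrays. It was 0.809, 0.377 and 0.484 in double-negative replicates 1 to 3. Forcing equal distributions of such ratios can alter the group difference itself. With replicate number as a block the adjusted count was again 0 and the unadjusted one 1709, with 771 higher and 938 lower. Over all 45037 probe sets 0 passed, and 2478 had an unadjusted p under 0.05, 1186 higher and 1292 lower, where chance gives 2252. Quantile normalization gave 1230, 472 higher and 758 lower, and the pseudocount of 1.75 gave 2473, 1627 higher and 846 lower. With the block 0 probe sets passed and 3562 had an unadjusted p under 0.05. Of the genes, 631 had all 3 double-positive values above and 651 had all 3 below the double-negative ones, 10.5% in all. Chance gives 10% if all arrays vary independently, and less if arrays of one replicate number share variation. The authors' deposited table gives p-values under 0.05 to 750 probe sets, 303 higher and 447 lower. That is 3.33% of its 22526 probe sets, where chance gives 1126. Of these, 305 changed at least 2-fold in that table, 71 higher and 234 lower, and 0 pass after Benjamini-Hochberg adjustment.

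Among the 8595 genes detected on all 6 arrays, tested with the replicate block, 95 genes passed the threshold, 34 higher and 61 lower (limma, Benjamini-Hochberg). Without the block 0 of the 8595 passed. The same blocked test on the 14140 probe sets with all 6 flags passed 5. These calls assume the pairing by replicate number, which is not shown beyond replicate 1. Sox2, a transcription factor of pluripotent cells, fell by 2.58 on the log2 scale (SE 0.192 in this blocked fit, 0.338 without block over all genes). The growth factor gene Gdf3 fell by 2.44 (SE 0.222). Asb4 rose by 3.22 (SE 0.239), Phlda2 by 2.51 (SE 0.189), Kdr by 2.62 and Cxcr4 by 2.47. The ligand genes Bmp2 (2.18) and Vegfc (1.41), the ETS factor gene Etv2 (2.04), Sox7 (1.71), the Notch effector gene Hey2 (1.44) and the hyaluronan synthase gene Has2 (1.79) also rose. Of the 95 genes, 28 belonged to the fixed lists, 12 of them higher and 16 lower. This combination of filter and block was added after the data had been seen, and the adjusted p of Cxcr4 in it was 0.0218 and that of Kdr 0.0413.

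The fixed lists held 375 places for measured genes. Adjusted over the list alone, 43 of these places, filled by 38 genes, passed the limma test, 14 higher and 29 lower; adjusted over all genes 0 passed. With the block 109 places passed, 53 higher and 56 lower, among them all 43. The count was 135 with array weights, 27 after quantile normalization and 9 with the trend and robust variance model. Those 9 were the 2 sort genes, 3 germ cell, 2 cardiac progenitor and 2 contractile genes, and 0 members of the other lists passed under that model. The count was 14 without double-positive replicate 2 and 14 without double-negative replicate 3, and 52 without both replicate 1 arrays. Camera found 8 of 28 lists shifted, 4 up and 4 down, and 12 with the block, 6 up and 6 down. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.21, and fry, which does not compare a list with other genes, passed 0 (smallest 0.11) without and 6 with the block. Those 6 were the trophoblast list (fry adjusted p = 0.03) and the pluripotency, cardiac progenitor, primordial germ cell, Wnt and p53 lists (0.045 each).

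**Figure D2:**
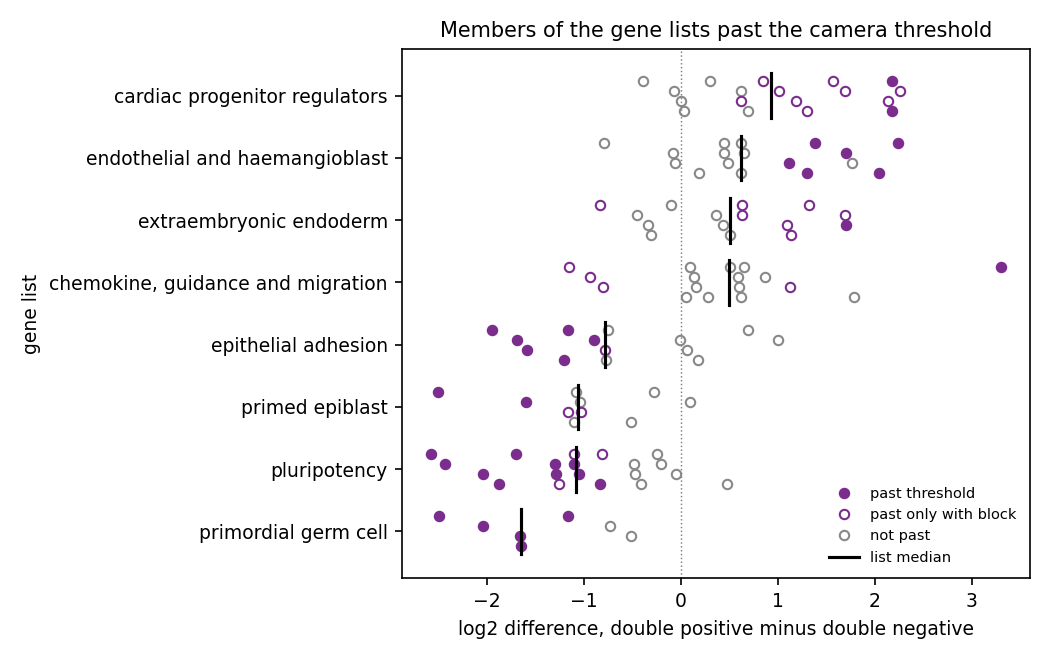
Log2 difference, double positive minus double negative, of each measured member (points, n = 3 arrays per group) of the 8 gene lists past the camera threshold. Filled points passed when adjusted over the list alone, open purple points passed only with the replicate block, and black bars are list medians, from -1.65 for the primordial germ cell list to 0.93 for the cardiac progenitor list.

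Pluripotency genes were lower in the double-positive cells. Of 20 measured members 10 fell when adjusted over the list alone and 0 over all genes, and 19 of 20 had a lower mean. Sox2 was 5.99-fold lower (log2 difference -2.58, SE 0.338), Gdf3 5.41-fold (-2.44, SE 0.376), Dppa3 4.14-fold (-2.05, SE 0.381) and Pou5f1, which encodes OCT4, 2.46-fold (SE 0.42 on the log2 scale). L1td1, Fbxo15, Klf2 (flags on 3 arrays), Zfp42, Dppa4 and Dppa5a also fell, by between 0.83 and 1.88. With the pseudocount of 1.75 Sox2 was at -0.54, Gdf3 at -0.55 and Dppa3 at -0.44. Nanog was at -1.26 (SE 0.477) and passed with the block, where 13 members did. The list median was -1.08 (camera adjusted p = 2.5e-14, and adjusted p = 0.21 with an estimated correlation). Left out in turn, double-positive replicates 2 and 3 and double-negative replicates 2 and 3 left 4, 5, 5 and 3 members past the threshold; 12 passed without both replicate 1 arrays. After quantile normalization 5 passed, and 0 with the trend and robust variance model.

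Germ cell and primed epiblast genes were lower too. Of 7 measured primordial germ cell genes 5 fell when adjusted over the list alone and 0 over all genes: Dnd1, an RNA-binding protein gene needed by germ cells, by 2.50 (SE 0.535), Dppa3, the transcription factor genes Prdm1 (-1.66, SE 0.574) and Tfap2c (-1.65, SE 0.343), and Ddx4. All 7 had lower means, with a median of -1.65 (camera adjusted p = 4.3e-09, and adjusted p = 0.4 with an estimated correlation). Of 10 primed epiblast genes 2 fell over the list alone and 0 over all genes. One of them, the TGF-beta family ligand gene Nodal, fell by 1.60 (SE 0.342). With the block 4 fell, among them Fgf5 and Pou3f1. The median was -1.06 (camera adjusted p = 1.7e-05, and adjusted p = 0.4 with an estimated correlation). The germ cell count was 3 when any one of double-positive replicates 1 and 2 and double-negative replicates 2 and 3 was left out. The epiblast list mean went from -1.02 to -0.68 without double-positive replicate 2. The epiblast count was 0 with the trend and robust variance model and without double-positive replicate 2 or double-negative replicate 2 or 3, 1 without double-positive replicate 1 and 4 without double-positive replicate 3. Without both replicate 1 arrays the counts were 6 and 2.

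Regulators of cardiac progenitors were higher in double-positive cells. Of 18 measured members 2 rose when adjusted over the list alone and 0 over all genes: Bmp2 (4.53-fold, log2 difference 2.18, SE 0.425) and the transcription factor gene Hand2 (4.53-fold, 2.18, SE 0.534). With the block 11 rose, among them the T-box genes Tbx2 (2.26, SE 0.794 without block), Tbx20 (2.13, SE 0.813) and Tbx3, the GATA factor genes Gata6 (1.69) and Gata4 (1.01), and Mesp1 (1.19). Isl1 was at -0.40 (SE 0.662) and Nkx2-5 at 0.03 (SE 0.361), and neither passed. The median was 0.93 with 16 of 18 means higher (camera adjusted p = 1.1e-07, and adjusted p = 0.4 with an estimated correlation). The count was 0 without double-positive replicate 2 or 3 or double-negative replicate 3, 6 without double-positive replicate 1 or double-negative replicate 2, 1 after quantile normalization and 3 without both replicate 1 arrays. Contractile genes of cardiomyocytes went both ways among 9 measured: Myl7 rose by 2.49 (SE 0.39), while the troponin gene Tnni3 fell by 2.85 (SE 0.68) and the alpha myosin heavy chain gene Myh6 by 1.37 (SE 0.302), over the list alone, and 0 passed over all genes. Myl7 passed flags on 4 arrays, Tnni3 on 3 and Myh6 on 2, and the other probe set of Myh6 pointed the other way. That list's mean was -0.15, its median 0.07 and its camera direction down (adjusted p = 0.76); 2 members passed without both replicate 1 arrays.

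Endothelial and haemangioblast genes were higher as well. Of 17 measured members 6 rose when adjusted over the list alone and 0 over all genes: the ETS factor genes Fli1 (4.72-fold, 2.24, SE 0.591) and Etv2 (4.12-fold, 2.04, SE 0.508), Sox7 (3.27-fold, 1.71, SE 0.393), Lmo2 (1.38, SE 0.442), Ramp2 (2.46-fold, SE 0.33 on the log2 scale) and the angiopoietin receptor gene Tek (1.11, SE 0.338). The other 3 probe sets of Ramp2 pointed the other way, and the mean over its probe sets was -0.32. Tal1 was at 1.76 (SE 0.765) and Cdh5, the cadherin gene of formed endothelium, at -0.08 (SE 0.301), and neither passed. The median was 0.62 (camera adjusted p = 2.4e-07, and adjusted p = 0.43 with an estimated correlation). The count was 0 after quantile normalization, with the trend and robust variance model and without double-positive replicate 2 or 3 or double-negative replicate 3, 2 without double-positive replicate 1, 3 without double-negative replicate 1 and 4 without both replicate 1 arrays.

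Globin genes led the haematopoietic list, on the lower side. Of 11 measured members 1 fell when adjusted over the list alone and 0 over all genes, the alpha globin gene Hba-a1 (-1.85, SE 0.409, flags on 3 arrays). The embryonic beta globin genes Hbb-y (-2.66, SE 1.15) and Hbb-bh1 (-2.49, SE 1.67) were lower in each of the 3 pairs. With the block 4 members fell, the 3 globin genes and Myb. Globin probes can share transcripts of paralogs. The list's median was -0.30 (camera adjusted p = 0.051, and 0.02 with the block; adjusted p = 0.71 and 0.49 with an estimated correlation). Hba-a1 no longer passed after quantile normalization, with the trend and robust variance model, without double-positive replicate 1 or 2 or double-negative replicate 1 or 2, nor without both replicate 1 arrays.

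Epithelial adhesion genes were lower in double-positive cells. Of 14 measured members 6 fell when adjusted over the list alone and 0 over all genes: Esrp1, a splicing regulator of epithelial cells (-1.95, SE 0.613), the tight junction genes Cldn7 (-1.69, SE 0.403) and Cldn4 (-0.90, SE 0.295), the E-cadherin gene Cdh1 (-1.59, SE 0.54), the desmosome gene Pkp2 (-1.21, SE 0.399) and Epcam (-1.17, SE 0.404). With the block 7 fell, Cldn6 (-0.78, SE 0.633) being the addition. The median was -0.78 (camera adjusted p = 0.00019, and adjusted p = 0.69 with an estimated correlation). The list mean went from -0.64 to -0.38 without double-positive replicate 1 and to -0.96 without double-negative replicate 1. The count was 0 with the trend and robust variance model and without double-positive replicate 1 or 2 or double-negative replicate 2 or 3, and 6 without both replicate 1 arrays. Of 16 mesenchymal genes 0 passed over the list alone or over all genes, and with the block Zeb1 and Zeb2, repressors of E-cadherin, rose. Without the block, 2 passed over the list alone when double-negative replicate 2 was left out. Zeb2 was at 1.24 (SE 0.384), with 2 of its 5 probe sets pointing the other way, and Pdgfrb at 1.15 (SE 0.654). That list's camera adjusted p was 0.076, and 0.03 with the block (adjusted p = 0.84 and 0.49 with an estimated correlation). Has2 was the 1 of 13 extracellular matrix genes that rose over the list alone (1.79, SE 0.44), and 0 passed over all genes (camera adjusted p = 0.25). It passed neither after quantile normalization, nor with the trend and robust variance model, nor without both replicate 1 arrays, nor without any single array other than double-negative replicate 2.

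The extraembryonic endoderm list was higher, with 1 of 15 measured members, Sox7, past the threshold over the list alone and 0 over all genes. With the block 7 rose and 1 fell: Sox7, Gata6, the basement membrane genes Col4a1 (1.32, SE 0.535) and Col4a2 (1.10, SE 0.503), Sparc, Ihh and Rbp4 rose, and Cited1 fell. The median was 0.51 (camera adjusted p = 0.0032, and adjusted p = 0.4 with an estimated correlation). Sox7 also stands in the endothelial list and Gata6 in the cardiac one. The list mean went from 0.50 to 0.18 with the 5'/3' control index as a covariate. Without double-negative replicate 1 it went to 0.13, and the member count was 0 there, after quantile normalization, with the trend and robust variance model, without double-positive replicate 2 or 3, without double-negative replicate 3 and without both replicate 1 arrays; it was 5 without double-negative replicate 2. Of 17 chemokine, guidance and migration genes 1 rose over the list alone, Ackr3, and 0 over all genes. Plxna2 was at 1.78 and Cxcl12 at 0.10 (SE 0.378). With the block Efnb2 rose too, and Slit2, Slit3 and Sema3a fell; the other 2 probe sets of Slit2 pointed the other way. Ackr3 did not pass with the trend and robust variance model or without both replicate 1 arrays. The median was 0.50 (camera adjusted p = 0.033, 0.068 with the block, and adjusted p = 0.71 with an estimated correlation). The list mean went from 0.46 to 0.17 without double-negative replicate 1 and to 0.71 without double-positive replicate 1. Its camera adjusted p was above the threshold without double-positive replicate 3 (0.096), double-negative replicate 1 (0.0531) or double-negative replicate 3 (0.0698), and without both replicate 1 arrays (0.0657). It was also above the threshold with the 5'/3' control index as a covariate.

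Primitive streak genes split. Nodal was the 1 of 15 that fell over the list alone, and 0 passed over all genes. With the block 3 rose, Mixl1 (1.71, SE 1.11), Eomes (2.83-fold, SE 0.722 on the log2 scale) and Pdgfra (1.91, SE 0.975), and 4 fell, Nodal, Fgf4, Fgf8 (-1.32, SE 0.507) and T, the brachyury gene (-1.34, SE 0.499). The 3 rises were largest in pair 1. In pairs 1 to 3 the log2 differences were 2.965, 1.109 and 1.061 for Mixl1, 2.546, 1.023 and 0.935 for Eomes, and 2.968, 1.37 and 1.382 for Pdgfra. T also fell most in pair 1, while Nodal, Fgf4 and Fgf8 did not. The list's mean was 0.18 and its median 0.34, while its camera direction was down (adjusted p = 0.99). Of 5 trophoblast genes Tfap2c fell over the list alone. With the block Gata3 (2.06, SE 1.20), Plac1 and Hand1 rose and Cdx2 fell as well. Gata3 was at 4.177, 0.878 and 1.121 in pairs 1 to 3. The trophoblast mean was 0.20 and median 0.62, with camera direction down (adjusted p = 0.89). Of 9 neuroectoderm genes 1 fell over the list alone (camera adjusted p = 0.14), while Otx2 was at -1.11. In the paraxial mesoderm (11 measured), definitive endoderm (16) and surface ectoderm (5) lists 0 members passed over the list alone and 1, 3 and 2 with the block; Cdx2, Cdh1, Epcam, Grhl3 and Tfap2a fell there and Dkk1 rose. Their camera adjusted p were 0.62, 0.42 and 0.18. Without the block, 1 definitive endoderm gene passed over the list alone without double-negative replicate 2, and 1 surface ectoderm gene without double-positive replicate 3 or without both replicate 1 arrays. Over all genes 0 members of these lists passed. Without both replicate 1 arrays the streak count over the list alone was 6 and the trophoblast count 4; the latter was 2 without double-positive replicate 1 or double-negative replicate 1 or 2. With the trend and robust variance model the streak, trophoblast and neuroectoderm counts were 0. Nodal did not pass in the streak list without double-positive replicate 2 or 3 or double-negative replicate 2 or 3. The streak count was 2 without double-negative replicate 1. The neuroectoderm count was 0 without double-positive replicate 1 or 2 or double-negative replicate 2 or 3, and 2 without double-positive replicate 3 or double-negative replicate 1.

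In the signalling lists 0 members passed without the block, over the list alone or over all genes. With it, 5 of 17 BMP and TGF-beta genes rose, among them Smad6 (1.37, SE 0.638), Bmp5 (1.45, SE 0.377) and Bambi (1.51, SE 0.474), and Id2 fell; camera gave an adjusted p of 0.051, and 0.044 with the block (adjusted p = 0.84 and 0.54 with an estimated correlation). Of 16 Wnt genes 4 rose with the block, Dkk1 (1.98, SE 0.526), Fzd7 (1.57, SE 0.545), Nkd1 and Apcdd1, and Wnt8a fell (camera adjusted p = 0.25). Of 11 Notch genes Hey1, Hey2, Hes1 and Nrarp rose with the block and Dll1 fell (camera adjusted p = 0.11). Of 9 Hox genes Hoxb6 rose and Hoxd9 fell with the block; the list's mean was -0.13 and its median 0.20 (camera adjusted p = 0.64, direction down). Without double-negative replicate 2, and with no block, 2 BMP and TGF-beta, 2 Wnt, 1 Notch and 1 Hox gene passed over the list alone; without both replicate 1 arrays 1 BMP and TGF-beta, 1 Wnt and 1 Hox gene did.

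Cell state lists held almost no member past the threshold. Of 22 cell cycle genes 0 passed over the list alone with or without the block, and 19 had a higher mean (median 0.14, camera adjusted p = 0.13, and 0.039 with the block; adjusted p = 0.84 and 0.54 with an estimated correlation). Of 9 p53 target and apoptosis genes 0 passed, with Sesn2 at -1.06 and a list median of -0.29 (camera adjusted p = 0.051, and 0.044 with the block; adjusted p = 0.73 and 0.49 with an estimated correlation). In the glycolysis (16 genes), oxidative phosphorylation (20) and immediate early and dissociation stress (15) lists 0 members passed either way, and 1 of 10 hypoxia genes, Bnip3, fell with the block. The camera adjusted p were 0.51, 0.14, 0.62 and 0.62 for glycolysis, oxidative phosphorylation, stress and hypoxia. The glycolysis mean was -0.06 and its median 0.01, and over all genes 0 members of these lists passed.

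Both replicate 1 arrays stood apart in the control probe sets. The 5'/3' ratio of Actb, relative to the double-negative median, was 0.278 in double-negative replicate 1 and 0.781 in double-positive replicate 1, against 0.987 to 1.12 in the other 4 arrays. For Gapdh the ratios were 0.216 and 0.634, against 0.956 to 1.05. The median log2 ratio of the probe sets in the authors' comparison table was -0.41 in double-positive replicate 1 and -0.33 in double-negative replicate 1, and between 0 and 0.11 in the others.

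**Figure D3:**
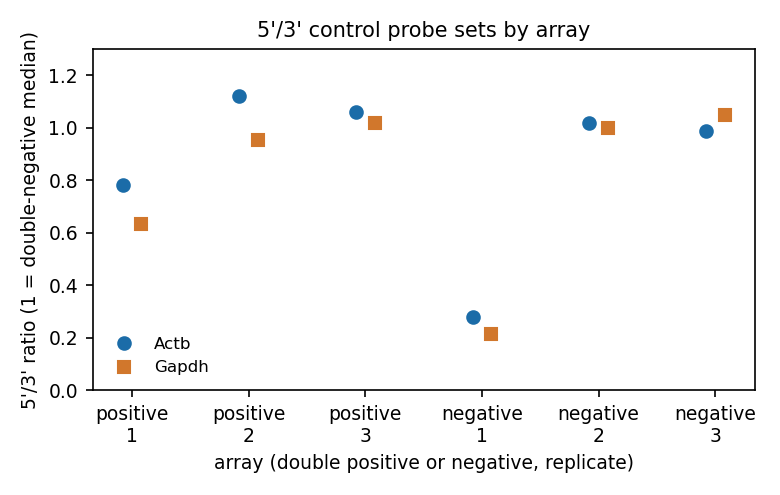
5'/3' ratio of the Actb (circles) and Gapdh (squares) control probe sets of each of the 6 arrays, on a linear axis where 1 is the double-negative median. Double-negative replicate 1 lay at 0.278 and 0.216 and double-positive replicate 1 at 0.781 and 0.634, below the other 4 arrays.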

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

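The pseudocount at the 10th percentile was foreseen as part of the scale and became an alternative once the values proved to be ratios. The flag filters, the fit without both replicate 1 arrays, the 5'/3' covariate and the count of list members under every setting were chosen after the data were seen, the other alternatives before. The brightness filters were not run. The replicate block (paired fit) left the adjusted counts of probe sets and genes at 0 and moved list members from 43 to 109. It moved lists past camera from 8 to 12 and changed no other camera call than those given with the block in the results. Joined with the restriction to probe sets with all 6 flags it gave 5 probe sets, all 5 of them at least 2-fold, 95 genes, 94 list members, and adjusted p values of 0.0218 for Cxcr4 (log2 difference 2.47) and 0.0413 for Kdr (2.62). Array weights gave 453 genes, 135 list members, and Cxcr4 at 2.44 (limma adjusted p = 0.00445) and Kdr at 3.25 (0.01). The pseudocount of 1.75 gave 6 genes, 13 lists and Cxcr4 at 1.47 (0.0112); the pseudocount of 0.437 gave 1 gene. List members numbered 27 after quantile normalization and 9 with the trend and robust model. Both settings act on ratios to the double-negative median, so how far that scale itself lowers these counts is open. The 5'/3' covariate gave 58 list members and 7 lists, the chemokine list no longer passing. An estimated correlation and fry each gave 0 lists. Over all alternatives Cxcr4 ran from 1.47 to 2.85 (adjusted p 0.00445 to 1) and Kdr from 1.66 to 3.35 (0.01 to 1), always higher in double-positive cells. Leaving out 1 array at a time gave 0 to 1 genes (1 without double-positive replicate 3), 8 to 13 lists (13 without double-positive replicate 1 or double-negative replicate 2) and 14 to 43 list members (14 without double-positive replicate 2 or double-negative replicate 3). The mean over a gene's probe sets turned Ramp2 to -0.32 and Egln3 to -0.12, neither past the threshold over all genes in either form. The cause of these shifts was not tested, except that a filter tests fewer genes and an omitted array leaves fewer samples. Signal over background is lost in the ratios, so how far dim probe sets drive large differences is unknown.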

Other observations

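The tests of explanations and of other splits without the block were set down before their results were seen; the comparisons of splits with the block, the genes of the next paragraph and the test behind them were chosen after the values were seen.

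Among the 95 genes past the threshold with the block and all 6 flags, those outside the fixed lists with large differences included Tmprss2 (-2.49, SE 0.275), Cpm (-2.12, SE 0.293) and Irs4 (-2.03, SE 0.2) on the lower side. On the higher side, besides Asb4 and Phlda2, stood Pmp22 (2.45, SE 0.369), the lipoprotein receptor gene Vldlr (2.02, SE 0.228), Rgs5 (1.98, SE 0.218) and Vstm2b (1.91, SE 0.182). Each had the same direction in all 3 pairs, which selection by a paired test favours, and no enrichment was tested among them.

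With 10 splits of the 6 arrays into 3 and 3, the share of splits with a result as large is never under 0.1. For probe sets changed, probe sets changed at least 2-fold and genes changed, the real value was 0 and the highest of the other splits 0, so 10 of 10 splits gave as many. For lists past camera the real value was 8 and the highest other 9, and 3 of the 10 splits gave as many. For list members over the list alone the real value was 43 and the highest other 29, and 1 of 10, the real one, gave as many. For probe sets of the authors' comparison table with an unadjusted p under 0.05 the real value was 1097 and the highest other 3165, and 5 of 10 gave as many. The split with 3165 joined both replicate 1 arrays with double-negative replicate 3, and the 3 other splits that kept both replicate 1 arrays together gave 1775 to 1997. These counts point to a structure of the samples in which both replicate 1 arrays stand apart; the splits that parted only the replicate 1 arrays, keeping the replicate 2 arrays together and the replicate 3 arrays together, gave 262 and 423. In the blocked fit, the real split is comparable only with the 3 others that part all 3 pairs. It gave 2761 probe sets against at most 1159, 109 list members against at most 1, and 95 against at most 0 genes with all 6 flags. So few splits cannot give a share near the threshold of 0.05.

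Without the block fewer of the 22526 probe sets had an unadjusted p under 0.05 (1097) than chance gives (1126), and with it there were 2761. Scaling of whole arrays is argued against as the whole cause, since centring each array on its median gave 1405, short of the 1.5-fold gain set beforehand. RNA integrity remains a candidate explanation: with the 5'/3' control index as a covariate the count was 2084. The highest of 100 shuffled indices gave 2074, but the shuffles cannot weigh this. The log2 index was -2.03 in double-negative replicate 1, -0.508 in double-positive replicate 1 and 0.0178 to 0.0551 in the others. A shuffle that leaves the replicate 1 values in place nearly repeats the real index. The index is set mostly by double-negative replicate 1, so anything else particular to that array stays open, its poly-A spike-in ratio of 2.22 included. The test of culture differences shared by both fractions of a replicate number could not tell. The difference between replicates 2 and 3 correlated at 0.056 between the groups. That is short of the 0.1 set beforehand for this cause but above the bound set against it. For the replicate 1 arrays, culture and integrity cannot be told apart.

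The globin transcripts Hbb-y, Hbb-bh1 and Hba-a1 were lower in double-positive cells in all 3 pairs. RNA integrity is argued against: in pairs 2 and 3, where the control ratios were close, the mean difference of Hbb-y, Hbb-bh1 and Hba-a1 was -1.97 (SD 0.35 over the genes) and -1.6 (SD 0.84), against -3.43 in pair 1. More erythroid cells among the double-negative ones may account for it, as a sort against FLK-1 and CXCR4 would leave them there, but the test did not settle this. The median of 15 other erythroid genes, of which 3 also stand in the haematopoietic list, averaged -0.15 over the pairs (-0.45, 0.08 and -0.06). The bound set beforehand for excluding erythroid cells was met but was wrong, because 11 of the 15 passed flags on at least 4 of 6 arrays, hence in both fractions, and such a baseline would hide a small share; Rhd (-1.08) and Epb42, with flags on 2 arrays, were lower in all pairs, Epb42 mainly in pair 2 (-0.45, -5.67 and -0.47), while Gata1 (-0.30), Klf1 (-0.24) and Trim10 (0.57, flags on 3 arrays) were not.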
